A study of Colpoda aspera with 2 samples.

How the data were processed

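Messenger RNA was sequenced from 2 samples of wild-type Colpoda aspera, a soil ciliate that forms resting cysts: 1 library of living (vegetative) cells and 1 library of encysting cells. Per the labels' protocols, cells grew at 30 °C in a dilute bacterial broth medium, encystment was induced by spinning the cells down and washing them in buffer, and most cells had made cysts within 24 h. The hour at which the encysting cells were lysed is not given in the sources used here. Per the labels' protocols, polyadenylated RNA was selected with oligo(dT) beads, made into strand-specific libraries and sequenced on an Illumina HiSeq instrument.

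The deposited values are FPKM, in which mapped fragments are divided by transcript length and by the library's mapped total, with 1 value per assembled transcript and library, per the file name and headers. Reads were trimmed with Trim Galore 0.4.0, per the submitters' processing notes. The assembler, aligner and quantifier are not given in the sources used here. The transcript identifiers have the form that Trinity, a de novo transcriptome assembler, gave its contigs: a component number, a subcomponent number and a sequence number. The table does not pair these identifiers with gene names, and no reference genome or annotation was used here, so genome positions and gene functions are not reported.

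FPKM values carry no read counts, so the depth of each library is unknown, and no counting interval or detection floor was computed. The values were checked for whole steps. Every deposited FPKM value of the living library was a whole multiple of 0.01. Every deposited FPKM value of the encysting library was a whole multiple of 0.0077, within a tolerance of 0.001 of its last decimal place. Such steps arise when values with 2 decimals are multiplied by 0.77, and no header or label records this multiplication or its purpose. The main comparison used the values as deposited, and the encysting values divided by 0.77 are given beside it as values with the constant undone.

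Transcripts were kept when their mean over both libraries was at least 1 FPKM. This mean was taken from the deposited values, also where the constant was undone or another scaling was applied. The ratio of encysting to living was taken as log2((encysting FPKM + 1)/(living FPKM + 1)). This scale understates the change of low transcripts. A transcript was counted as higher or lower when this ratio reached 1 or -1, a 2-fold difference. Both sample titles end in the number 2, and any library with another number was not analysed here. With 1 library per group there is no replicate check, so the difference between the groups was not tested and no p-value is given. All counts describe these 2 libraries and not the 2 conditions. The interval given with a median ratio is a 95% interval from the binomial distribution of ranks across transcripts, which are not independent replicates, and it does not cover differences between cultures.

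Before the data were examined, a rule fixed which transcripts would be named. Among kept transcripts with at least 0.1 FPKM in both libraries, the 10 highest and the 10 lowest ratios were to be named if gene names could be attached, together with the 5 highest transcripts of each library, the 2 most abundant members of each gene list, and up to 3 transcripts per direction listed at 0 in a single library. Because names could not be attached, the rule printed only 2 identifiers per direction and gave the others as values without identifiers. For the same reason 0 of the 29 gene lists fixed in advance could be tested. They covered ribosomes, translation, cilia, proteolysis, chaperones, antioxidant enzymes, energy metabolism, the cell cycle, signalling, transport and cyst wall candidates among others. A separate list of bacterial genes, fixed as a check of other cells in the culture, could not be tested either.

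To compare the depth of the libraries, the ratios of low transcripts were searched for read steps. Among transcripts at 0.5 to 1.5 FPKM in both libraries (constant undone), the share whose ratio lay within 1% of a ratio of whole numbers from 1 to 4, multiplied by a common factor, was computed for a series of such factors. The factor with the highest share estimates how many FPKM 1 fragment is worth in the encysting relative to the living library. FPKM values were also summed per subcomponent, the identifier without its sequence number.

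The alternatives were pseudocounts of 0.1 and 5 FPKM, no filter, a minimum mean of 5 FPKM, scaling to equal sums, scaling to equal sums without the 20 highest transcripts, scaling to equal upper quartiles, centring of the median ratio, and a 4-fold threshold. Undoing the constant, summing per subcomponent and keeping only single-member subcomponents were added after the data had been seen. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, with plots from Matplotlib 3.10.9. The 2-fold threshold was tested on simulated data for 28782 transcripts, with depth and transcript lengths assumed. The simulated ratios were centred on their median, which was not done in the main comparison. Among the simulated transcripts, 100 were changed 4-fold and 100 were changed 8-fold. The threshold was passed by 80.0% of the former and 91.0% of the latter. It was passed by 100.0% of those with a baseline of at least 5 FPKM in either set. Of the 28582 simulated transcripts left unchanged, 0.32% passed the threshold by counting error alone. This share depends on the assumed depth and lengths, so it does not give the counting error of these 2 libraries.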

Results

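The transcriptome of the ciliate Colpoda aspera was compared between living cells and cells undergoing encystment, with 1 library of each. Encystment is the change from a swimming, feeding ciliate to a dormant, walled cyst. The table listed 49543 assembled transcripts in 33326 components and 37166 subcomponents, a subcomponent being the assembler's nearest equivalent of a gene. Of these subcomponents, 32220 held a single transcript and 4946 held 2 or more, up to 119. FPKM values summed to 1216994 in the living library and to 953367 in the encysting library. The lower encysting sum reflects a constant of 0.77 found in every encysting value. With that constant undone the encysting sum was 1238139.

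The number of sequenced fragments is unknown, but the relative FPKM value of 1 fragment could be read from low transcripts. Among 3588 transcripts at 0.5 to 1.5 FPKM in both libraries, 20.3% had ratios on whole-number steps when 1 fragment was taken as worth 1.185 times as many FPKM in the encysting library (constant undone) as in the living library. The median share over all tried values, which ran from 0.8 to 1.6, was 7.5%. The 95% bootstrap interval of the 1.185 over transcripts was 1.18 to 1.19. These are the tried values next to 1.185, so the spacing of the tried values limits how precise the interval can be. If the length used for each transcript was the same in both libraries, the living library held about 1.185 times as many mapped fragments. The steps of 0.0077 place the constant after rounding to 2 decimals, and this reading takes the rounded values as FPKM. With the constant left in, the same step was 0.912, a value that also contains the constant. Part of the transcripts in this range therefore rested on a few fragments, so their ratios carry a large counting error. At 1.5 to 5 FPKM the share at that value was 8.9% against a median of 8.3%, and the steps could no longer be seen.

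**Figure D1:**
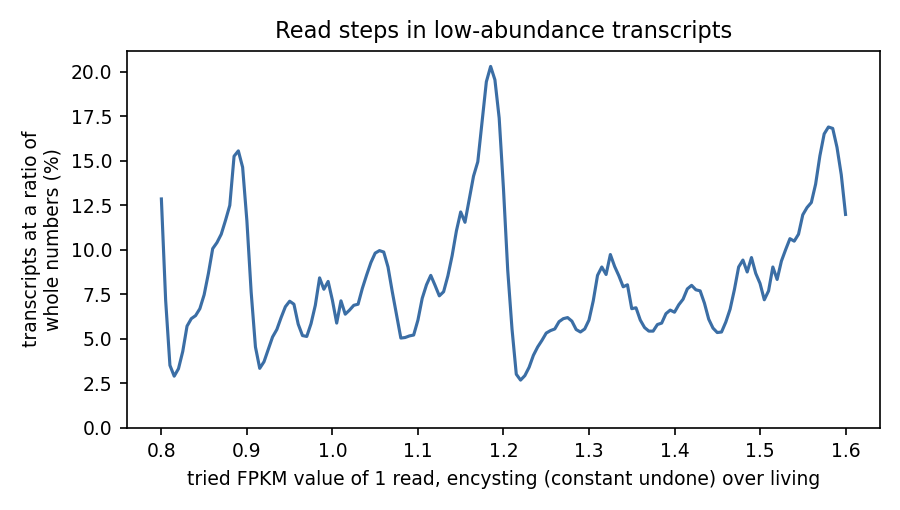
Share of the 3588 transcripts at 0.5 to 1.5 FPKM in both libraries (vertical axis, percent) whose ratio lay within 1% of a ratio of whole numbers from 1 to 4, for each tried FPKM value of 1 fragment in the encysting relative to the living library (horizontal axis). The line peaks at 20.3% where the tried value is 1.185; the lower peaks at 0.89 (15.6%) and 1.58 (16.9%) lie where whole-number ratios of that value fall.

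More transcripts had a value in encysting cells alone than in living cells alone. The living library listed 12194 transcripts at 0 (24.6%) and the encysting library 10849 (21.9%), and 8565 were listed at 0 in both. In encysting cells 3629 transcripts had a value while they were listed at 0 in living cells, and the reverse held for 2284 transcripts. Most of these were of low abundance. The median of the former was 1.15 FPKM in encysting cells and that of the latter 1.18 FPKM in living cells. Of the transcripts listed at 0 only in living cells, 397 (10.94%) reached at least 5 FPKM in encysting cells. The 3 highest of them had 127.09, 75.66 and 57.16 FPKM. Of those listed at 0 only in encysting cells, 295 (12.92%) reached at least 5 FPKM in living cells. The 3 highest of them had 93.08, 81.91 and 68.18 FPKM.

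Of the 100 highest transcripts of each library 76 were the same, of the 50 highest 40, of the 10 highest 4 and of the 5 highest 2. The 100 highest held 30.32% of the summed FPKM in living cells and 27.54% in encysting cells, and the 10 highest held 5.32% and 5.00%. The highest transcript of both libraries had 7932 FPKM in living and 5837 FPKM in encysting cells. The second highest of living cells had 7654 FPKM there and 1215 FPKM in encysting cells. The other 3 of the 5 highest in living cells had 7332, 6184 and 6155 FPKM, against 4878, 3045 and 2408 FPKM in encysting cells. In the other direction, the second and the third highest of encysting cells had 5758 and 4896 FPKM, against 3272 and 1363 FPKM in living cells. The fourth was the transcript at 7332 FPKM in living cells, and the fifth had 4796 FPKM against 4399 FPKM. Among the 100 highest of living cells, 20 were at least 2-fold lower and 0 at least 2-fold higher in encysting cells. Among the 100 highest of encysting cells, 12 were at least 2-fold higher and 6 at least 2-fold lower there. These folds are on the deposited scale, and the counts for these sets were not made with the constant undone. Each set was picked by high values in the library it is named for, which favours lower values in the other library. The 20 against 0 and the 12 against 6 were therefore shaped by this choice, and no conclusion is drawn from them.

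Many transcripts differed by 2-fold or more, in nearly equal numbers in each direction on the deposited scale. Of 28782 transcripts with a mean of at least 1 FPKM, 4146 (14.4%) were at least 2-fold higher in encysting cells, 4520 (15.7%) were at least 2-fold lower, and 20116 lay within 2-fold. At 4-fold the numbers were 1266 higher and 1294 lower. The median log2 ratio was 0.002 (95% interval -0.011 to 0.015 across transcripts), with quartiles of -0.63 and 0.61. Across these transcripts log2(FPKM + 1) correlated between the libraries with Pearson's r = 0.825, and FPKM with Spearman's rho = 0.713. Transcripts are not independent replicates.

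The balance of higher and lower transcripts depended on the constant and on the low transcripts. With it undone, 6435 transcripts were at least 2-fold higher and 3186 at least 2-fold lower in encysting cells, so that 66.9% of the transcripts past the threshold were higher, against 47.8% as deposited. The median log2 ratio moved to 0.308 (95% interval 0.294 to 0.320). Scaling both libraries to a sum of 1000000, which also lowered the living values against the pseudocount, gave 5884 higher and 3110 lower (65.4% higher). Scaling the encysting values alone to equal sums without the 20 highest transcripts gave 6056 and 3341 (64.4% higher). Equal upper quartiles gave 4844 higher and 4036 lower (54.5% higher). On the deposited scale the balance moved the other way when low transcripts weighed less. A minimum mean of 5 FPKM gave 1645 higher and 2776 lower (37.2% higher), and a pseudocount of 5 FPKM gave 38.6% higher. With 1 library per group, none of these numbers can be set against the spread between cultures.

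**Figure D2:**
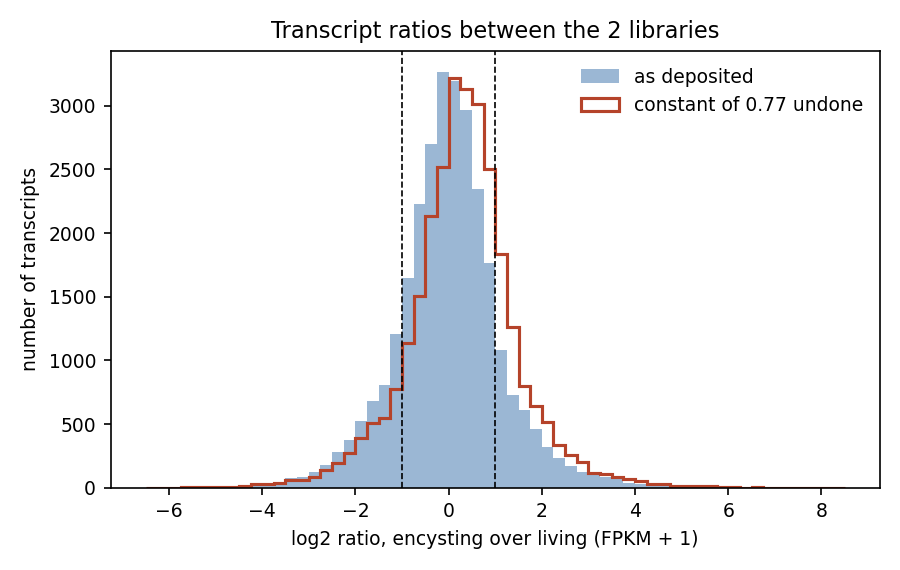
Number of transcripts (vertical axis) by log2 ratio of encysting over living FPKM + 1 (horizontal axis, bins of 0.25) for the 28782 transcripts with a mean of at least 1 FPKM. Filled bars are the values as deposited (median 0.002), the outline those with the constant undone (median 0.308), and the dashed lines mark 2-fold.

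Abundant transcripts were lower in encysting cells relative to rare ones. The median log2 ratio was 0.14 for the 15300 transcripts with a mean of 1 to 5 FPKM, -0.07 for the 7760 at 5 to 20 FPKM and -0.24 for the 4099 at 20 to 100 FPKM. It was -0.52 for the 1446 transcripts at 100 to 1000 FPKM and -0.60 for the 177 at 1000 FPKM or more. At 1 to 5 FPKM 2501 transcripts were at least 2-fold higher and 1744 lower, and at 5 to 20 FPKM 1015 were higher and 1378 lower. At 20 to 100 FPKM 462 were higher and 962 lower, and at 100 to 1000 FPKM 161 were higher and 408 lower. At 1000 FPKM or more 7 were higher and 28 lower. With the constant undone the medians of these 5 ranges were 0.40, 0.27, 0.12, -0.14 and -0.22. The ranges were still set by the mean of the deposited values. The order of the ranges thus stayed while the sign of the ranges at 5 to 20 and at 20 to 100 FPKM flipped. The undone values put 3762 transcripts higher and 1334 lower at 1 to 5 FPKM, and 1669 and 955 at 5 to 20 FPKM. They put 757 higher and 648 lower at 20 to 100 FPKM, 232 and 236 at 100 to 1000 FPKM, and 15 and 13 at 1000 FPKM or more.

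**Figure D3:**
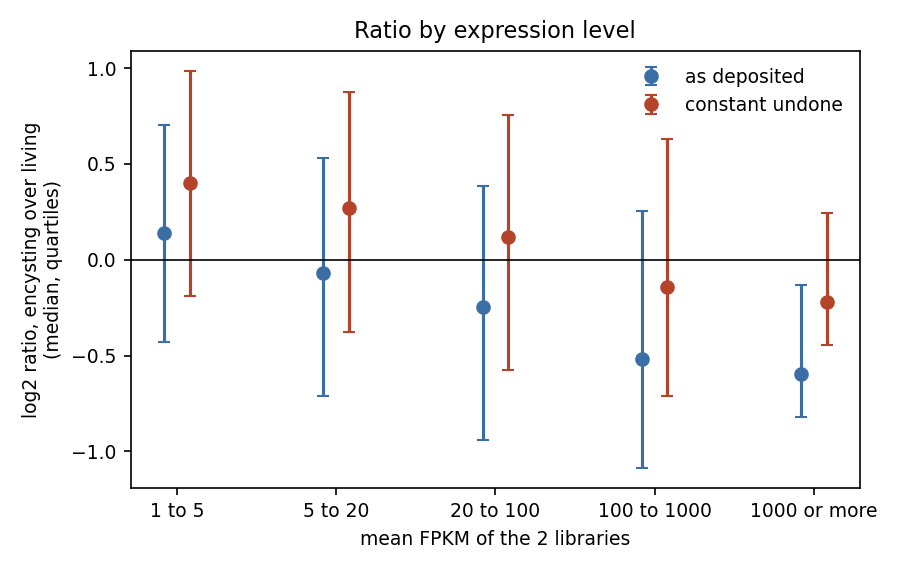
Median log2 ratio of encysting over living FPKM + 1 (vertical axis, bars span the quartiles across transcripts) in 5 ranges of mean FPKM (horizontal axis). The mean is that of the 2 libraries as deposited for both sets of points. Blue points are the values as deposited, from 0.14 down to -0.60, and red points those with the constant undone, from 0.40 down to -0.22.

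Among kept transcripts with at least 0.1 FPKM in both libraries, a limit that leaves out those listed at 0, the highest ratio belonged to comp16310_c0_seq1. comp16310_c0_seq1 had 0.13 FPKM in living cells and 346 FPKM in encysting cells, a log2 ratio of 8.26. comp23388_c0_seq1 had 0.59 FPKM in living cells and 325 FPKM in encysting cells, a log2 ratio of 7.68. Within this limit the 10 highest ratios, from 5.83 to 8.26, came from 7 subcomponents, and these transcripts had 0.13 to 3.25 FPKM in living and 86.2 to 429.8 FPKM in encysting cells. One subcomponent gave 3 of the 10. All 15 of its transcripts were at least 2-fold higher in encysting cells, 3 of them were listed at 0 in living cells, and their FPKM summed to 18.5 in living and 841 in encysting cells. This subcomponent was picked out after its values had been seen.

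In the other direction, comp5862_c1_seq1 had 252.85 FPKM in living and 2.21 FPKM in encysting cells, a log2 ratio of -6.31. comp5862_c0_seq1, from another subcomponent of the same component, had 600.01 and 8.87 FPKM, a log2 ratio of -5.93. Among transcripts with at least 0.1 FPKM in both libraries, the 10 lowest ratios, from -6.31 to -4.31, came from 10 subcomponents of 8 components, with 24.2 to 600.01 FPKM in living and 0.27 to 8.87 FPKM in encysting cells. Undoing the constant left the 4 named transcripts at log2 ratios of 8.64, 8.06, -6.04 and -5.59, in the order given here. The number of fragments behind their lower values is unknown, so the size of these folds is uncertain.

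The same counts were made for subcomponents. Of 22109 subcomponents with a mean summed FPKM of at least 1, 3290 (14.9%) were at least 2-fold higher in encysting cells and 3655 (16.5%) at least 2-fold lower, with a median log2 ratio of -0.005. Undoing the constant made these 5134 and 2589. Among 3504 subcomponents with 2 or more kept transcripts, all members were at least 2-fold higher in 181 and all at least 2-fold lower in 246. In 86 of them (2.5%) a transcript that was at least 2-fold higher stood beside another that was at least 2-fold lower, and in 73 of these 86 the summed FPKM lay within 2-fold. How reads shared between such transcripts were divided is not given in the sources used here, so their separate values are uncertain.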

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

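Undoing the constant and the subcomponent settings were chosen after seeing the data. Over 12 alternatives, 15 of the counts of higher or lower transcripts lay within 1.5 times the deposited counts of 4146 and 4520, and 9 did not. The 9 came from a pseudocount of 5 FPKM (1463 higher, 2327 lower), a mean of at least 5 FPKM (1645 and 2776), the 4-fold threshold (1266 and 1294), single-member subcomponents of at least 5 FPKM (1033 and 2013) and the higher count with the constant undone (6435). The smaller counts follow from a stricter rule or fewer transcripts. The median log2 ratio left its interval under scaling to equal sums (0.276), upper quartiles (0.101), sums without the 20 highest (0.266), the constant undone (0.308), a mean of at least 5 FPKM (-0.171) and the last limit with single-member subcomponents only (-0.189). Pearson's r became 0.887 with no filter and 0.698 with a pseudocount of 0.1, and Spearman's rho was 0.713. The set with no filter includes the 8565 transcripts listed at 0 in both libraries, which have equal values by definition. The ratios of comp16310_c0_seq1 (6.10 to 10.56), comp23388_c0_seq1 (5.89 to 8.88), comp5862_c1_seq1 (-6.77 to -5.16) and comp5862_c0_seq1 (-6.06 to -5.45) kept their sign in all 10 alternatives each. The alternatives for gene lists were not run, since names could not be attached. No paired analysis was possible because each group has 1 library. Unknown depth limits the reading of transcripts near 1 FPKM.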

Other observations

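The tests of the constant, of the pseudocount and of depth against the zeros were chosen after closely related values had been seen. Those on subcomponents were set before their results were seen.

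The ratios of separate contigs of a component were correlated. This was tested because the 2 lowest ratios among transcripts with at least 0.1 FPKM in both libraries came from 1 component. In 1557 components with at least 2 subcomponents above the filter, the log2 ratios of the 2 most abundant subcomponents correlated across components with Pearson's r = 0.477 and Spearman's rho = 0.55. Over 100 random pairings r ranged from -0.05 to 0.06. At 5 FPKM or more in both subcomponents r was 0.597 over 776 components. Among the 529 components whose most abundant subcomponent differed by 2-fold or more, the other did so in the same direction in 46.7% and in the opposite direction in 5.29%. Over 100 random pairings these shares averaged 14.7% and 14.3%, and ranged from 10.2% to 18.0% and from 11.2% to 17.8%. The correlation lay above chance pairing. It says nothing about variation between cultures, since both contigs come from the same 2 libraries, and reads shared between the contigs would also raise r. Whether the contigs of a component were pieces of 1 transcript was not tested, and random pairing across components cannot tell.

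The purpose of the constant of 0.77 stays open. The median ratio of living to unscaled encysting values, over 35065 transcripts above 0 in both libraries, was 0.767, and a trimmed mean of log ratios over 12777 of them gave 0.753. Both restate that the median ratio of the deposited values was close to 0 on the log2 scale, so they are not independent evidence of how the constant was chosen.

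The lower ratio at 100 FPKM or more than at 5 to 20 FPKM was not removed by the processing changes tried. Without a pseudocount, the median log2 ratio at 100 FPKM or more minus that at 5 to 20 FPKM was -0.450 (95% bootstrap interval across transcripts -0.515 to -0.394). After summing over the isoforms of each subcomponent it was -0.448 (-0.518 to -0.381). The second value argues against splitting of reads between isoforms as the whole of the difference between these 2 ranges. The first shows that the difference is present without a pseudocount. It cannot decide whether the pseudocount shapes the decline as a whole, since 1 FPKM adds little at 5 FPKM or more. The range of 1 to 5 FPKM, where the pseudocount weighs most, was not compared. Without a pseudocount, undoing the constant shifts every ratio by the same amount. A difference in library preparation between the 2 samples and the change from living to encysting cells both stay open, since 1 library per group does not separate them.

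The encysting library listed fewer transcripts at 0, 10849 against 12194. Assignment of reads between isoforms of 1 subcomponent does not account for the whole of this. After summing, 2895 subcomponents were listed at 0 only in living cells and 1844 only in encysting cells. The ratio was 1.57 (95% exact binomial interval 1.48 to 1.67, for counting of subcomponents only). Since 32220 of the 37166 subcomponents held a single transcript, summing left most values unchanged. Division of reads between subcomponents of a component is not covered. A deeper encysting library would not account for the fewer zeros either, under 2 assumptions. These are that the values before the constant were FPKM and that each transcript's length was the same in both libraries. The living library then held about 1.185 times as many fragments (95% bootstrap interval 1.18 to 1.19, limited by the spacing of the tried values). A wider low-level transcript background in the encysting sample, RNA from other organisms in the culture, and a larger set of expressed genes during encystment were not tested. This list is not complete. Which reads the transcripts were assembled from was not examined, and 8565 transcripts were listed at 0 in both libraries.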
